A study of Mus musculus with 12 samples.

How the data were processed

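RNA from cumulus cells and mural granulosa cells of unprimed and eCG-stimulated mice was measured on 12 arrays, 3 for each of the 4 groups. Per the labels, the mice were B6SJLF1 animals 22 days old, each cumulus sample came from 200 cumulus-oocyte complexes, and each pool held 5 mice. Per the labels' protocols, 20 ng of total RNA was amplified in consecutive rounds before hybridization, a step that can alter relative levels and favours the 3′ end of transcripts.

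The authors deposited log2 values per probe set. Per the submitters' processing notes these were made with RMA in the affy package. RMA corrects background, applies quantile normalization between arrays and summarises probes by median polish, so array distributions are made alike and a change shared by most transcripts is removed. The versions, the array model, the probe set definition, the genome build and the annotation release are not given in the sources used here. The deposited log2 values had array medians of 7.30 to 7.38. No pair of arrays held more than 0.0386% identical values, so all 12 were kept as separate samples. All columns of values belonged to the 12 samples.

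The table held 41179 probe sets, of which 64 were the manufacturer's controls and 41115 carried Ensembl mouse transcript identifiers, with 27365 distinct sets of values. Identical values on all arrays mean that these transcripts cannot be told apart here, and counts of distinct sets are given beside the main counts. The files do not pair the identifiers with gene names. The RefSeq gene table of assembly GRCm38.p6 held 0 Ensembl identifiers, so 0 probe sets were matched to a gene. The planned unit of 1 probe set per gene was therefore replaced by each probe set on its own, and the planned tests of gene lists (among them cumulus and mural markers, steroidogenesis, cholesterol synthesis, glycolysis, cell cycle, and markers of oocytes, theca, stroma, endothelium and leukocytes) were not run. Contamination by other cell types was for that reason not tested. For naming, the planned rule took the transcripts with the largest and smallest log2 change among those past the threshold whose 3 replicates in one group all lay above the 3 of the other, and it was limited to 2 in each direction because no gene names were at hand. For the interaction the rule took the largest and smallest values past the threshold.

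A probe set was tested where its value lay above the array's 40th percentile on at least 3 of the 12 arrays, which kept 25917 and left out 15198. One linear model with a mean for each group was fitted to all 12 arrays with lmFit and eBayes in limma 3.58.1 (R 4.3.3), so the groups shared an estimate of the spread. The contrasts were cumulus minus mural in unprimed and in stimulated mice, stimulated minus unprimed in cumulus and in mural cells, and the interaction, which is the difference between the last 2. Adjusted p-values are Benjamini-Hochberg values over 25917 probe sets per contrast, with a threshold of 0.05. The 64 control probe sets were fitted along with the tested probe sets in a separate run and adjusted over 64. The distance between the cell types was tested with an exact permutation of the stimulation labels within each cell type. Overlaps of calls were set beside the number from independent lists. The contrasts compared shared no arrays, but cumulus and mural arrays may share pools of mice, so the lists of stimulation effects may not be independent. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

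The procedure was tested on simulated data made from the real spread, with 200 of 25917 probe sets changed. At a log2 change of 1 it recovered 91.0% for unprimed cumulus against mural cells, 97.0% for stimulated cumulus against mural cells, 97.0% for stimulation in cumulus cells, 98.5% for stimulation in mural cells and 79.1% for the interaction. At a log2 change of 0.5 these shares were 31.3%, 26.9%, 31.3%, 41.8% and 5.97%. The simulated runs held 5 to 8 false calls each. In this setting small changes, above all in the interaction, were often missed with 3 arrays per group. The data gave 839 to 10825 calls per contrast, and more changed probe sets make the adjusted threshold less strict. The simulated noise was also independent between probe sets. These shares and numbers of false calls therefore do not carry over directly to the data.

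Replicate numbers were shared between groups, and the labels do not say that a number marks a shared pool. Deviations from the group means correlated between unprimed cumulus and mural arrays of the same number (0.11, 0.31 and 0.42), above the limit of 0.1 set for pairing. Between stimulated cumulus and mural arrays the correlations were 0.19, 0.14 and -0.13, between unprimed and stimulated cumulus arrays 0.21, 0.036 and 0.12, and between unprimed and stimulated mural arrays -0.092, -0.54 and -0.48. All pairs therefore passed the limit in the unprimed comparison of the cell types only. Arrays of unlike number were not compared, so this does not show that the number marks a pairing. For the unprimed comparison, a fit with the replicate block called 2380 higher and 2615 lower probe sets. A replicate block within each stimulation state called 2932 and 3179.

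The alternatives tried, chosen before the data were examined, were no filter or a 60th percentile filter, median centring, renewed quantile normalization, cyclic loess, a fit of only the 6 arrays compared, eBayes with trend and robust settings, array weights, an added limit of 1 on the log2 change, an adjusted p under 0.01, replicate blocks and leaving out each array in turn. Added after the data were seen were a fit to distinct sets of values, a covariate for RNA length (the mean 3′ minus 5′ difference of the Gapdh and beta-actin controls) and a covariate for the mean of the 24 dap, lys, phe and thr control probe sets.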

Results

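Gene expression was measured with Affymetrix arrays in 2 kinds of granulosa cell from mouse ovarian follicles, before and after gonadotropin stimulation. Cumulus cells surround the oocyte, and mural granulosa cells line the follicle wall. Stimulated mice received 5 IU of equine chorionic gonadotropin (eCG, also called PMSG), a hormone with follicle-stimulating activity, 44 hours before collection, and unprimed mice received none. All mice were 22 days old. Each of the 4 groups (cumulus or mural cells, unprimed or stimulated) held 3 arrays, described by the labels as biological replicates from pools of 5 mice. The median log2 value per array lay between 7.30 and 7.38, and the number of arrays limits the precision. Of 41115 probe sets named by Ensembl transcript, 25917 passed the filter on low values, and these held 16809 distinct sets of values because some transcripts shared identical values on all arrays. The files do not pair these transcripts with gene names, so at most 2 that were higher and 2 that were lower are given by identifier for each comparison, and counts describe the rest.

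The 12 arrays fell into their 4 groups. The first principal component held 46.1% of the variance and placed all cumulus arrays on one side (-38.3 to -33.1) and all mural arrays on the other (18.6 to 54.2). The second held 27.4% and placed the unprimed arrays (10.8 to 45.8) apart from the stimulated arrays (-35.6 to -9.02). Correlations between replicates lay between 0.984 and 0.986 in stimulated cumulus cells, 0.990 and 0.993 in unprimed cumulus cells, 0.987 and 0.989 in stimulated mural cells, and 0.972 and 0.987 in unprimed mural cells. The unprimed mural arrays were the most spread of the 4 groups along the second component, with replicate 2 nearest to the stimulated arrays.

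**Figure D1:**
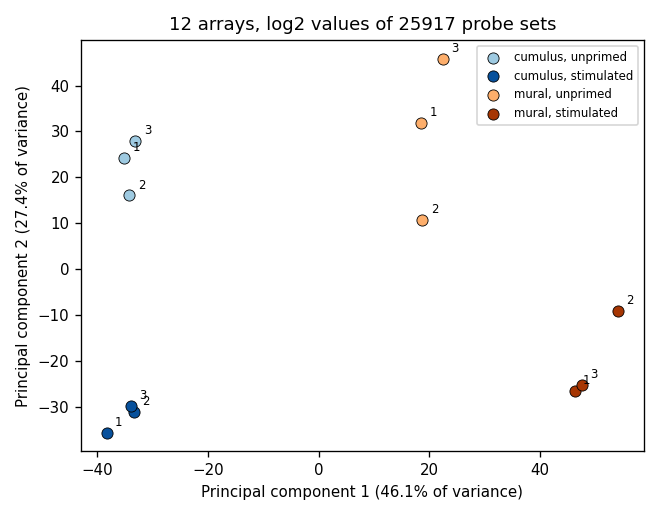
Positions of the 12 arrays on the first 2 principal components of the log2 values (component scores, with the percent of variance on each axis). Each point is 1 array, coloured by group and numbered by replicate. Cumulus arrays lie at -38.3 to -33.1 on the first component and mural arrays at 18.6 to 54.2.

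Cumulus and mural cells of unprimed mice were compared to ask how far the cell types had already diverged before stimulation. Cumulus cells had higher values for 2719 probe sets and lower values for 2793 of the 25917 tested (1899 and 1739 when identical sets of values were counted once). Large differences lay mostly on the mural side, with 131 probe sets at least 2-fold higher in cumulus cells and 533 at least 2-fold higher in mural cells. The transcript ENSMUST00000003640 was higher in cumulus cells, at 11.23 ± 1.04 (SD, n = 3) against 6.13 ± 0.11 in mural cells (log2 difference 5.10 ± 0.44 SE, adjusted p = 2.4e-05), the mural value being below the filter level of those arrays (6.69 to 6.73), so no fold is given. ENSMUST00000107094 was also higher in cumulus cells, with a log2 difference of 3.44 ± 0.29 (adjusted p = 2.4e-05). ENSMUST00000039631 was higher in mural cells, at 10.51 ± 0.42 against 7.71 ± 0.06, a log2 difference of -2.80 ± 0.22 (adjusted p = 1.8e-05). ENSMUST00000147615 had a log2 difference of -3.40 ± 0.85 (adjusted p = 0.015), and without mural unprimed replicate 1 this was -2.84 (adjusted p = 0.063). Its cumulus value of 4.23 ± 0.14 lay at the level of the trpn controls. With each array centred on its median, 61.5% of the called probe sets were higher in cumulus cells, against 49.3% as deposited, 49.8% after renewed quantile normalization and 40.4% after cyclic loess. The number higher in cumulus cells was 1547, 1456 and 1480 without unprimed cumulus replicates 1, 2 and 3 and 1539 without unprimed mural replicate 1, and the number lower was 1694, 1770 and 1817 without cumulus replicate 1, cumulus replicate 3 and mural replicate 1.

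After stimulation more probe sets were called in the same comparison. Cumulus cells had higher values for 6090 probe sets and lower values for 4735 (4118 and 2990 distinct), which together made up 41.8% of those tested against 21.3% in unprimed mice. Of the called probe sets 56.3% were higher in cumulus cells, and this share was 61.1% with median centring, 53.3% after renewed quantile normalization and 49.5% after cyclic loess. The order of these counts turned with array weights, which called 5832 higher and 4701 lower in stimulated mice against 6913 and 6176 in unprimed mice. These weights were 8.61 for unprimed mural replicate 1 and 0.492 and 0.369 for replicates 2 and 3, so that group then rested largely on 1 array. Differences of at least 2-fold numbered 742 higher and 874 lower in cumulus cells, and those of at least 4-fold numbered 75 and 165. The 2 transcripts with the largest excess in mural cells were ENSMUST00000003659 and ENSMUST00000024916. The first lay at 13.19 ± 0.33 in mural and 6.94 ± 0.57 in cumulus cells (SD, n = 3; log2 difference -6.25 ± 0.28 SE, adjusted p = 3.3e-08), and the second lay at 10.71 ± 0.43 against 4.92 ± 0.53 (-5.79 ± 0.32, adjusted p = 1.4e-07). The cumulus value of the first was close to the filter level of those arrays (6.66 to 6.72), and that of the second was near the trpn control probe sets, which have no mouse target (means of 4.51 to 4.57), so no fold is given. ENSMUST00000003640 was again far higher in cumulus cells, by 4.65 ± 0.44 on the log2 scale (adjusted p = 8.9e-06). Its mural value of 5.95 ± 0.19 lay below the filter level of the stimulated mural arrays (6.69 to 6.71), so this size is not exact. ENSMUST00000033023 followed with 3.92 ± 0.20 (adjusted p = 1.1e-07) and shared its values with 1 other transcript. Its mural value of 6.81 ± 0.37 was close to the filter level of those arrays, so this size is not exact either. The dap, lys, phe and thr control probe sets, which detect polyadenylated bacterial RNAs commonly added to samples before amplification, were also higher in stimulated cumulus arrays. All 24 were called, with a median log2 difference of 1.00 and a range of 0.62 to 1.40. With the mean of these controls as a covariate, chosen after the data were seen, 559 probe sets were higher and 976 lower. These were fewer than the 2488 and 3034 called in unprimed mice in that fit. For stimulated mice the standard errors were 2.26 times as large in the median. The log2 differences of stimulated mice had a slope of 0.864 on those without the covariate (r = 0.734).

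Many of the differences between the cell types had one direction at both stages. Of the probe sets called, 4081 (2731 distinct) had the same direction before and after stimulation, where independent lists of these lengths would share 1149, and 23 had opposite directions. With the covariate of added controls 1207 had the same direction, and with array weights 6691. The log2 differences correlated across probe sets (r = 0.73), which are not independent replicates. The distance between the cell types was larger after stimulation. The root mean square of the log2 differences between group means was 0.392 in unprimed and 0.545 in stimulated mice, and exchanging the stimulation labels within each cell type gave a difference as large as the observed 0.154 in 2 of 400 assignments (two-sided exact permutation p = 0.005, the smallest possible). This permutation tests for no stimulation effect at all, not for an equal distance alone. It also exchanged the labels of the cell types separately. If cumulus and mural arrays of one number shared a pool, fewer assignments would be valid and this p-value would be too small. Corrected for noise, the distance was 0.359 and 0.522, with ranges of 0.350 to 0.369 and 0.504 to 0.533 when 1 array was left out. It was 0.394 and 0.521 with array weights, and 0.377 and 0.545 with the covariate of added controls. The number shared by both stages was 2513, 2641 and 2521 without unprimed cumulus replicates 1, 2 and 3, and 2619 without unprimed mural replicate 1.

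**Figure D2:**
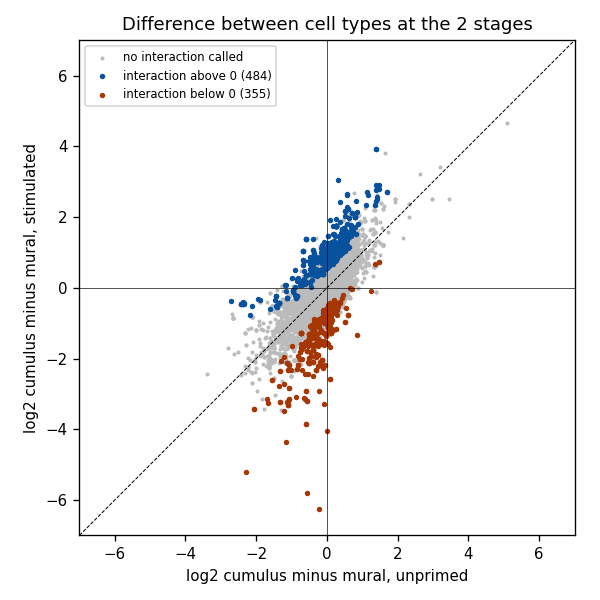
Log2 difference between cumulus and mural cells in unprimed mice (horizontal axis) and in stimulated mice (vertical axis) for 25917 probe sets, from 3 arrays per group. Blue and red points are the 484 and 355 probe sets whose difference became higher or lower with stimulation by the test of the interaction, grey points are all others, and the dashed line marks equal differences.

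In cumulus cells, the comparison of stimulated with unprimed mice gave 2734 higher and 2393 lower probe sets (1802 and 1529 distinct). Changes of at least 2-fold numbered 330 upward and 218 downward. ENSMUST00000099575 rose 8.10-fold, from 8.35 ± 0.35 to 11.37 ± 0.31 (SD, n = 3; log2 change 3.02 ± 0.29 SE, adjusted p = 5.6e-05), and ENSMUST00000038197, which shared its values with 1 other transcript, rose by 2.98 ± 0.32 on the log2 scale (adjusted p = 0.00012). ENSMUST00000016602, which shared its values with 5 other transcripts, fell from 8.62 ± 0.13 to 5.66 ± 0.47 (log2 change -2.96 ± 0.22, adjusted p = 9.6e-06). ENSMUST00000094022 fell from 9.32 ± 0.68 to 6.40 ± 0.01 (-2.92 ± 0.24, adjusted p = 2.5e-05). The stimulated values of both lay below the filter level of those arrays (6.66 to 6.72), so the size of these falls is not exact. Mural cells changed in the same direction in each of these 4 transcripts, with log2 changes of 3.45, 2.68, -2.50 and -2.72. The added bacterial RNA controls were higher in stimulated than in unprimed cumulus arrays as well, in 24 of 24 probe sets (median log2 difference 0.92). The bioB, bioC, bioD and cre controls, commonly added at hybridization, were higher too, with 14 of 18 called and a median of 0.42. With the mean of the dap, lys, phe and thr controls as a covariate 16 probe sets were higher and 22 lower, and the standard errors were 2.14 times as large in the median. In that fit the log2 changes of the 4 transcripts were 2.15, 1.95, -2.95 and -3.02, and none was called. The number higher was 1761, 1793, 1626 and 1437 without stimulated replicates 1 and 2 and unprimed replicates 1 and 3. The number lower was 1182, 1356, 1341, 1362 and 1033 without stimulated replicates 1 and 2 and unprimed replicates 1, 2 and 3.

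In mural cells, stimulation was followed by higher values in 1697 probe sets and lower values in 2218 (1086 and 1403 distinct). Changes of at least 2-fold numbered 426 upward and 390 downward. Array weights called 3755 higher and 4817 lower. ENSMUST00000003659 rose from 6.78 ± 0.48, close to the filter level of those arrays (6.69 to 6.73), to 13.19 ± 0.33 (SD, n = 3; log2 change 6.41 ± 0.28 SE, adjusted p = 1.5e-07). ENSMUST00000024916 rose from 5.23 ± 0.66, near the trpn controls (4.42 to 4.51), to 10.71 ± 0.43 (5.48 ± 0.32, adjusted p = 9.1e-07). ENSMUST00000026084, which shared its values with 1 other transcript, fell from 10.84 ± 0.40 to 7.24 ± 1.37 (-3.60 ± 0.50, adjusted p = 0.00042), and ENSMUST00000025390 fell from 9.77 ± 0.26 to 6.37 ± 0.90, below the filter level (-3.39 ± 0.33, adjusted p = 2.2e-05). Of the 24 added bacterial RNA controls limma called 0 between the mural groups (1 at an unadjusted p under 0.05), with a median log2 difference of 0.15. The number higher was 1080 without stimulated replicate 1, and the number lower was 1410 without stimulated replicate 1 and 1477 without unprimed replicate 1. With the 3′ minus 5′ difference of the Gapdh and beta-actin controls as a covariate, chosen after the data were seen, 1096 were higher.

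**Figure D3:**
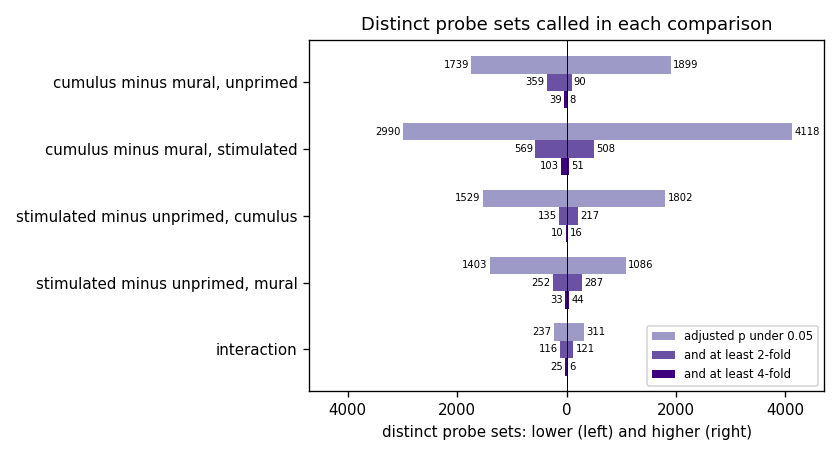
Number of distinct probe sets called lower (left) and higher (right) in each comparison at an adjusted p under 0.05 (light bars), and of those the number that differed by at least 2-fold (middle) and 4-fold (dark). The interaction is the difference between the stimulation effects in cumulus and mural cells.

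Part of the stimulation effect was shared between the cell types. In the 2 cell types together, 1550 probe sets (982 distinct) changed in the same direction, where independent lists would share 383.8, and 81 changed in opposite directions. The labels do not say whether cumulus and mural arrays share pools of mice, which could raise the shared number. With the covariate of added controls, which left 38 calls in cumulus cells, 30 changed in the same direction, and with array weights 2713. The log2 changes correlated across probe sets (r = 0.54). The number with the same direction was 968 and 954 without unprimed cumulus replicates 1 and 3.

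The test of the interaction asked which probe sets responded differently to stimulation in cumulus and mural cells. It called 839 probe sets, of which 484 had a higher log2 change in cumulus than in mural cells and 355 a lower one (311 and 237 distinct). The sign does not give the cell type with the stronger response. Of the 311, 174 were called lower in mural cells and 169 higher in cumulus cells. Of the 237, 182 were called higher in mural cells and 69 lower in cumulus cells. The absolute change was larger in mural cells in 345 of the 548 distinct probe sets. Among the 548 distinct probe sets, 269 were called in mural cells alone, 178 in cumulus cells alone, 47 in both with the same direction and 50 in both with opposite directions. The difference between the cell types grew in 492 and shrank in 56. The largest effects were transcripts that rose in mural cells. Of 25 distinct probe sets with an interaction of -2 or below on the log2 scale, 24 rose in mural cells and 19 of these had no called change in cumulus cells. ENSMUST00000003659 and ENSMUST00000024916 led this group with interactions of -6.02 ± 0.40 (SE, adjusted p = 2.1e-05) and -5.21 ± 0.45 (adjusted p = 9.5e-05), and their log2 changes in cumulus cells were 0.39 ± 0.28 and 0.27 ± 0.32. In all groups but stimulated mural cells, values of the first lay close to or below the filter level and those of the second near the trpn controls, so the sizes of these interactions and their rank are not exact. ENSMUST00000038069 had the highest positive interaction, 2.74 ± 0.46 (adjusted p = 0.0067), with a rise from 7.32 ± 0.72 to 9.84 ± 0.16 (SD, n = 3) in cumulus cells and values of 7.01 ± 0.56 and 6.79 ± 0.34 in mural cells. The stimulated mural value was close to the filter level of those arrays (6.69 to 6.71), so the size of this interaction is not exact. ENSMUST00000033023 rose in cumulus cells by 0.74 ± 0.20 and fell by 1.78 ± 0.20 in mural cells (interaction 2.53 ± 0.28, adjusted p = 0.00049). Its stimulated mural value was close to the filter level, so the size of this interaction is not exact. With the mean of the added bacterial RNA controls as a covariate the interaction called 50 higher and 127 lower, and ENSMUST00000038069, at 2.24, was no longer called.

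The interaction counts moved when single arrays were left out. A group then holds fewer arrays, so falls are expected from lost power, but rises are not. Without stimulated mural replicate 1, 414 of the remaining calls were called the same way with all arrays. The number higher was 227 and 298 without stimulated mural replicates 1 and 2, 237 and 230 without unprimed cumulus replicates 1 and 3, 288 and 982 without unprimed mural replicates 1 and 3, and 318 without stimulated cumulus replicate 2. The number lower was 193 without stimulated mural replicate 1, 204, 220 and 202 without unprimed cumulus replicates 1, 2 and 3, 222 without unprimed mural replicate 1, and 562 without stimulated cumulus replicate 3.

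**Figure D4:**
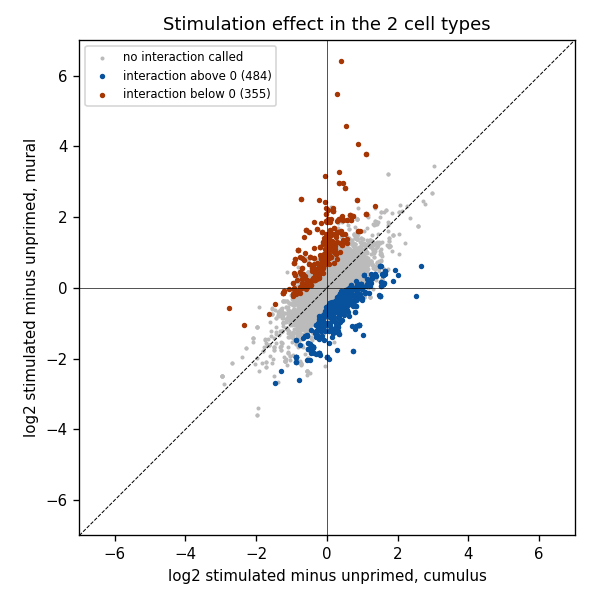
Log2 change with stimulation in cumulus cells (horizontal axis) and in mural cells (vertical axis) for 25917 probe sets, from 3 arrays per group. Blue and red points are the 484 and 355 probe sets with a higher or lower change in cumulus than in mural cells by the test of the interaction, and the points highest on the vertical axis are transcripts that rose by up to 6.41 in mural cells.

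Control probe sets with names gave values for a few mouse genes. The 3′ probe set of pyruvate carboxylase, the enzyme that makes oxaloacetate from pyruvate, was lower in cumulus than in mural cells of stimulated mice, at 7.51 ± 0.24 against 8.58 ± 0.12 (SD, n = 3; log2 difference -1.07 ± 0.12 SE, adjusted p = 2.3e-05 over 64 control probe sets). It fell in cumulus cells with stimulation by 0.38 on the log2 scale (adjusted p = 0.013), and its log2 difference in mural cells was 0.38 (adjusted p = 0.12). Both had a standard error of 0.12 and an unadjusted limma p under 0.05. The 64 adjusted together include the added bacterial RNA and hybridization controls, of which 24 and 14 were called in cumulus cells and 0 in mural cells. This lowers adjusted p-values in cumulus cells, so a control probe set called there alone does not show a response of cumulus cells alone. The interaction of the 3′ pyruvate carboxylase probe set was -0.76 ± 0.17 (adjusted p = 0.013), and the calls of this probe set held under median centring, renewed quantile normalization and cyclic loess. For the control probe sets only these scalings were tried. The covariate of added controls, array weights and leaving out an array were not tried for them. The other 3 pyruvate carboxylase probe sets were not called in any comparison. The 5′ probe set of Gapdh, a glycolytic enzyme, rose in cumulus cells by 0.51 (adjusted p = 0.022), also under the 3 other scalings, while its 3′ probe set differed by 0.17 (adjusted p = 0.067). The middle Gapdh probe set was called in cumulus cells as deposited (0.22, adjusted p = 0.048) and with median centring, but not after renewed quantile normalization (adjusted p = 0.095) or cyclic loess (adjusted p = 0.060). The Gapdh 3′ minus 5′ difference was -0.33 in stimulated against unprimed cumulus arrays (exact permutation p = 0.1, the smallest possible with 3 arrays against 3) and -0.36 in mural arrays (exact permutation p = 0.3). That of beta-actin was 0.16 in cumulus arrays (exact permutation p = 0.3) and -0.03 in mural arrays (exact permutation p = 0.6), and the mean of both, the length covariate, differed by -0.08 (exact permutation p = 0.6) and -0.20 (exact permutation p = 0.3). In mural cells the Gapdh 5′ difference was 0.61 and the middle one 0.35 (adjusted p = 0.12 for both), with adjusted p-values of 0.048 and 0.045 after renewed quantile normalization and 0.031 for both after cyclic loess. The 3′ probe set of 18S ribosomal RNA fell in cumulus cells by 0.45 (adjusted p = 0.0091) under all 4 scalings, and its log2 difference in mural cells was -0.39 (adjusted p = 0.14). The limma interactions of the Gapdh 5′ and the 18S 3′ probe sets were -0.11 (adjusted p = 0.80) and -0.06 (adjusted p = 0.86), so no difference between the cell types was called. The other 2 probe sets of 18S ribosomal RNA were not called in cumulus cells, with log2 differences of -0.02 (5′, adjusted p = 0.84) and -0.10 (middle, adjusted p = 0.50).

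**Figure D5:**
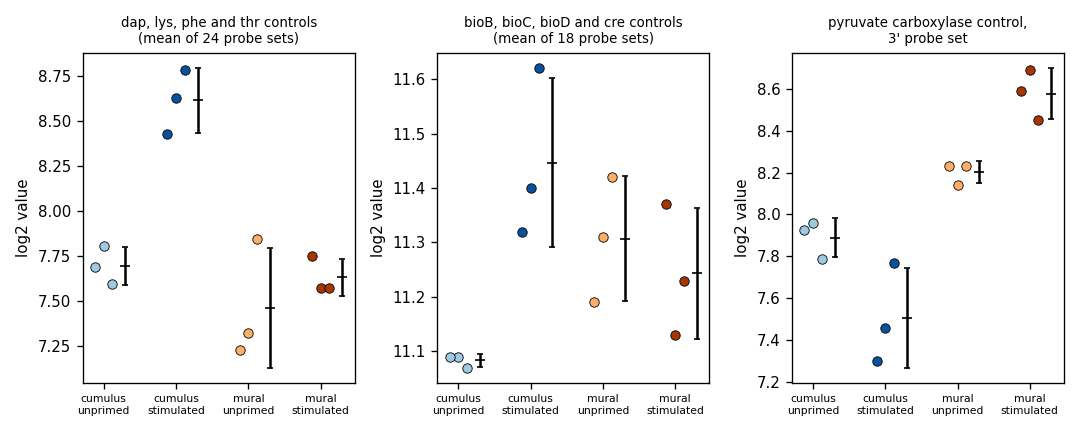
Log2 values on each array of the dap, lys, phe and thr controls (left, mean of 24 probe sets), the bioB, bioC, bioD and cre controls (middle, mean of 18) and the 3′ pyruvate carboxylase probe set (right). Points are single arrays and bars give the mean and SD of 3 arrays per group. The 3 stimulated cumulus arrays lie between 8.43 and 8.79 on the left, above the other 9 arrays.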

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

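Tests chosen only after the result was seen were the share of the interaction with the larger change in each cell type, the 3 tests of the added RNA controls, and the order of the unprimed arrays along the stimulation effect. The tests of RNA length and the counts of other splits were fixed before their results were seen.

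By the test of the interaction, the log2 change with stimulation was higher in cumulus than in mural cells in 484 probe sets and lower in 355. A higher change can also be a fall in mural cells. The extreme values were 2.74 for ENSMUST00000038069, 2.53 for ENSMUST00000033023, -6.02 for ENSMUST00000003659 and -5.21 for ENSMUST00000024916. In all groups but stimulated mural cells the third lay close to or below the filter level and the last near the trpn controls, so neither size is exact. The first and the second lay close to the filter level in stimulated mural cells, so their sizes are not exact either. The 3′ probe set of pyruvate carboxylase differed in its response by -0.76. The added dap, lys, phe and thr controls differed by a median of 0.83 (20 of 24 called) and the bioB, bioC, bioD and cre hybridization controls by a median of 0.47 (12 of 18 called).

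For each comparison of 3 arrays with 3, only 1 of the 10 splits, the real one, called as many probe sets, which is too few splits for a share under 0.05. The real counts were 5512 for the cell types in unprimed mice, 10825 in stimulated mice, 5127 for stimulation in cumulus cells and 3915 in mural cells, and the highest of the other splits gave 0, 1, 3 and 18. For the interaction, 3 of 100 splits within each cell type called as many as the real 839, the real one included, with 5247 as the highest other. This share does not exclude chance, although it lies under the limit set beforehand, because exchanging the labels breaks up the stimulation effect itself and so does not test the interaction alone. All 81 splits that mixed the labels of both cell types called 0, and the 18 that mixed those of 1 cell type called 20 to 5247. A split that mixes 1 cell type keeps the stimulation effect of the other in the contrast, so a high count can follow from that alone. Why splits of the same kind differed so much was not tested.

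The first pattern was that cumulus and mural cells differed more after stimulation. A technical difference of the stimulated cumulus arrays alone could put the larger change in cumulus cells. If it damped a response shared by both cell types, it would instead leave the mural change larger. Among the distinct probe sets with an interaction, the mural change was the larger one in 62.96% and the cumulus change in 37.04%. These shares therefore cannot decide. Such a difference cannot be told apart from biology, because it would lie in the same arrays. The ratio of the noise-corrected distance after stimulation to that before was 1.479 with the length covariate and 1.46 without it. The covariate differed between cumulus and mural arrays by only 0.04 in stimulated and -0.08 in unprimed mice. Between the stimulated arrays its Gapdh and beta-actin parts went opposite ways, at -0.19 and 0.26. This fit could therefore hardly move the ratio, and RNA length stays open. A divergence of the cell types under eCG remains a hypothesis, and cells of other types were not tested.

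The second pattern was the higher level of the added dap, lys, phe and thr controls in stimulated cumulus arrays. Hybridization or scanning was argued against as the whole cause. Minus the hybridization controls, these controls lay 0.7833 higher (log2) in the stimulated cumulus arrays (-2.89 to -2.77) than in the mean of the other 9 (-4.00 to -3.29). The hybridization mean includes cre controls with high values that moved little, so this size is not exact. The hybridization controls moved as well, so a part of the difference may lie there. Between stimulated and unprimed cumulus arrays they rose by 0.09 to 0.575 (14 of 18 called), against 0.566 to 1.364 for the dap, lys, phe and thr controls. In the interaction the ranges overlapped, at 0.095 to 0.669 and 0.337 to 1.045. Between stimulated cumulus and mural arrays the hybridization controls differed by 0.01 to 0.43. All 24 of 24 dap, lys, phe and thr control probe sets were higher than in stimulated mural arrays, by 0.62 to 1.40. This may reflect a lower share of mRNA in the sample or more control RNA added, and these values cannot separate them. With their mean as a covariate the log2 changes of cumulus cells had a slope of 0.464 on those without it, and a transcript such as ENSMUST00000099575 went from 3.02 ± 0.29 to 2.15 ± 0.59, while ENSMUST00000016602 and ENSMUST00000094022 gave -2.95 and -3.02, against -2.96 and -2.92, from stimulated values below the filter level, and lost the call with larger standard errors. The standard errors were 2.14 times as large in the median. The stimulated cumulus arrays all hold high values of the covariate, so its part in the cumulus response cannot be told apart from stimulation. The fit takes the covariate's effect from its spread within groups, which was largest in unprimed mural arrays (SD 0.332, against 0.178, 0.105 and 0.103). There replicate 2, nearest to the stimulated arrays, had the highest mean (7.842, against 7.319 and 7.225). The fit may thus take out part of the stimulation effect, and 0.464 does not measure an effect of the mRNA share.

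The third pattern was weak and concerned the unprimed arrays. Placed along the stimulation effect of the other cell type, where 1 is the full effect, unprimed cumulus and unprimed mural arrays had the same order, with replicate 2 nearest to the stimulated state (0.066 and 0.26). The ranges were 0.1089 in cumulus cells and 0.49 in mural cells, which is consistent with pools of mice whose follicles differed in stage, but a shared order of 3 arrays is too likely by chance to decide it. After the RNA length slope was taken out the smaller range was 0.06597 and the mural range 0.37, and the shared order was lost (cumulus replicates 1, 2 and 3 at 0.025, 0.016 and -0.041, mural at -0.068, 0.22 and -0.15), so RNA length stays open.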

How the results depend on the processing

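The RNA length covariate, the covariate of added control RNAs and the fit to distinct sets of values were chosen after the data were seen, and the other alternatives before. For the 20 named values, 261 of 267 alternatives kept direction and call, 6 lost the call (4 of cumulus stimulation and 1 of the interaction with the control RNA covariate, 1 at an adjusted p under 0.01) and 0 reversed. Leaving out an array kept 143 of 144 and lost 1. Counts of calls stayed within 1.5 times in 103 of 144 alternatives and in 40 of 72 left-out arrays.

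Pairs of values are numbers higher and lower. Array weights, which gave unprimed mural replicate 1 a weight of 8.61, called 6913 and 6176 for the cell types in unprimed mice, against 5832 and 4701 in stimulated mice, 3755 and 4817 for stimulation in mural cells and 1900 and 1291 for the interaction, with 6691 shared in direction by the stages and 2713 by the cell types. With a log2 change of at least 1 the counts were 131 and 533 for the cell types in unprimed mice, 742 and 874 in stimulated mice, 330 and 218 for stimulation in cumulus cells, 426 and 390 in mural cells and 191 and 178 for the interaction, with 433 shared in direction by the stages and 229 by the cell types. At an adjusted p under 0.01 the counts in that order were 821 and 1208, 4012 and 3016, 1111 and 769, 886 and 1117, and 140 and 139, with 1505 and 586 shared. The stricter limits call fewer by construction. The RNA length covariate gave 1096 higher for stimulation in mural cells. The covariate of added control RNAs gave 559 and 976 for the cell types in stimulated mice, 16 and 22 for stimulation in cumulus cells and 50 and 127 for the interaction, with standard errors 2.26, 2.14 and 1.47 times as large, and 1207 and 30 shared. Distinct sets of values, fewer by construction, gave 1738 lower for the cell types in unprimed mice, 2988 lower in stimulated mice, 1776 and 1503 for stimulation in cumulus cells, 1074 and 1379 in mural cells, 306 and 236 for the interaction and 964 shared in direction by the cell types. Unprimed mural replicates 2 and 3 had array weights of 0.492 and 0.369, so that group then rested largely on 1 array. Comparisons without unprimed mural arrays moved less with array weights. They called 5832 and 4701 for the cell types in stimulated mice and 3324 and 2996 for stimulation in cumulus cells. The cause of the shift with array weights was not tested further.

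With 1 array left out, which also lowers the power, the cell types in unprimed mice gave 1456 to 2765 higher and 1694 to 2824 lower. Stimulation gave 1437 to 2462 higher and 1033 to 2570 lower in cumulus cells, and 1080 to 2037 higher and 1410 to 2184 lower in mural cells. The interaction gave 227 to 982 higher and 193 to 562 lower. Calls shared in direction numbered 2513 to 4047 for the stages and 954 to 1995 for the cell types. For the cell types in stimulated mice the ranges, 4584 to 5433 and 3783 to 4708, stayed within 1.5 times. The distance between mural groups moved to 0.405 without unprimed mural replicate 2, from 0.365.

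Fits with the replicate block changed no call of a named transcript and no count by more than 1.5 times. For example, the replicate block called 5800 and 4614 for the cell types in stimulated mice, 2467 and 2049 for stimulation in cumulus cells, 1568 and 2069 in mural cells and 400 and 286 for the interaction. Not run for lack of gene names were the tests of gene lists with their variants and the choices of 1 probe set per gene. Transcripts near the low end of an array's values carry compressed changes, and how many is limited by signal over background.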
